A study of Danio rerio with 18 samples.

How the data were processed

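Gene expression was measured on 18 single-channel microarrays of sorted cells from zebrafish embryos of the AB strain that carried 2 reporters, a GFP driven by the Runx1+23 enhancer and a DsRed2 driven by the kdrl promoter. Embryos were treated from 2 to 3 days post fertilization (dpf) with 75 µM Lycorine in 1% DMSO, or with 1% DMSO alone. Lycorine is an alkaloid of Amaryllidaceae plants that is known to inhibit protein synthesis. Cells were dissociated enzymatically and sorted into 3 fractions, called here Runx+ (the enhancer reporter of hematopoietic stem and progenitor cells, HSPC), kdrl+ (the endothelial reporter) and negative (neither colour). RNA was amplified and biotin-labelled before hybridization. Each of the 6 combinations of treatment and sort had 3 arrays, numbered 1 to 3 in the labels. The labels call these biological replicates but do not say that arrays sharing a number came from 1 pool of embryos, nor that the 3 numbers of a treatment were separate pools. If they were not, the p-values measure only the spread between these samples, which can be technical.

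The deposited table holds log2 values for 65528 probe rows on all 18 arrays. The submitters' processing notes name oligo, RMA and limma, with versions not given in the sources used here, so the log2 values are taken to be background-corrected, quantile-normalized and summarised by the authors with RMA. The values ranged from 1.53 to 13.32, and the median of an array lay between 4.87 and 5.12. No arrays held identical values, and the highest correlation between any pair was 0.984. Of the rows, 20806 carried exactly 1 gene symbol, 855 carried several and 43867 carried none. Rows with 1 symbol were matched to current names through a RefSeq gene table of the assembly GRCz12tu (20323 by Entrez identifier, 72 by symbol, 43 by synonym), and 368 kept the name of the array annotation. No coordinates were taken from that table. For the 1372 genes with more than 1 row, the row with the highest mean over all arrays was used, which left 19247 genes. Dim genes were not filtered.

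Genes were tested with limma 3.58.1 in R 4.3.3 by a fit of 6 group means to all 18 arrays with moderated variances (lmFit, contrasts, eBayes, 2-sided). P-values were adjusted by the Benjamini-Hochberg method over all genes within a contrast, with a threshold of 0.05. There were 9 contrasts, made of 3 between sorts in DMSO, 3 between Lycorine and DMSO within a sort, and 3 differences of Lycorine effects between sorts. A contrast between sorts shares 3 DMSO arrays with the Lycorine contrast of either sort, so these are not independent. The total degrees of freedom were 17.4, and the median standard error (SE) of a log2 difference was 0.27 for the 6 direct contrasts and 0.38 for the differences of effects. The number of arrays, 3 per group, limits this precision. Spread was unequal between treatments. The root mean square SD of genes within a group was 0.44, 0.54 and 0.5 in DMSO negative, Runx+ and kdrl+ cells. With Lycorine it was 0.26, 0.33 and 0.27. The fit pools these into 1 variance per gene, so SE and p-values of contrasts between DMSO sorts tend to be too small. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and figures drawn with matplotlib 3.10.9.

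Of the 34 gene lists, 33 could be tested, because no member of the mitochondrially encoded list was measured by a named row. The lists held 1064 genes, of which 955 (89.8%) were measured. They covered blood and vessels (HSPC markers, erythroid, myeloid, lymphoid, thrombocyte, endothelial, HSPC niche adhesion and chemokines), other tissues that a sort can hold (skeletal muscle, neural, retina and lens, epidermis, neural crest and pigment, liver with pancreas and gut, mesenchyme and cartilage), and cell processes. The processes were DNA replication, mitosis, p53 targets, the integrated stress response, endoplasmic reticulum (ER) chaperones, heat shock, cytosolic ribosomal proteins, ribosome biogenesis, inflammation, interferon-stimulated genes, immediate early genes, sterol synthesis, xenobiotic and oxidative stress, hypoxia and glycolysis, the circadian clock, nuclear-encoded oxidative phosphorylation, the proteasome, translation factors and the Notch pathway. Some genes stand in more than 1 list. Among them are itga2b in the HSPC and thrombocyte lists, lmo2 and tal1 in the HSPC and endothelial lists, and cxcl8a in the niche and inflammation lists. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast, and again with the correlation estimated from the data. Camera compares the members of a list with all other genes. List members past the gene test were counted over all genes tested and also adjusted over the list alone. Array scores of a list are the mean over its members of the log2 difference from each gene's mean over the 18 arrays.

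The groups, the tests, the lists, the rule for named genes and the first alternatives below were fixed before the data were examined. The rule named, for each direct contrast, the 10 largest rises and 10 largest falls among genes past the threshold whose arrays did not overlap between groups, or the 5 genes with the smallest p where fewer than 5 passed. For differences of effects it took 5 each way under the same provision. It added runx1, kdrl and itga2b in every contrast between sorts, up to 4 members with the smallest p of each list described, and niche genes past the test adjusted over that list alone in a Lycorine contrast. Symbols that are only clone or locus identifiers were counted but not named. The 7 genes named for Lycorine in kdrl+ cells are given in the other sorts too, a choice made after their values were seen.

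The first alternatives were the replicate number as a fixed block, the presumed embryo pool as a random block, a fit to the compared arrays alone, an intensity trend with robust variances, array weights, cyclic loess, median centring, filters that left 14435 or 9624 genes, the mean of a gene's rows, every row tested on its own, a fold threshold of 2, each array left out in turn, and the sort contrasts among the Lycorine arrays. Added after the data were seen were the 3 same-numbered DMSO arrays left out together, the 9 Lycorine arrays alone in the fit, the mean of the DMSO and Lycorine contrasts, and a test on the mean of the 3 same-numbered arrays of a treatment. Every array carries equal weight in the main test.

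Whether equal numbers pair the arrays was checked from correlations across genes of the residuals of same-numbered arrays in the groups compared. These were all above 0.1 for kdrl+ versus negative in DMSO (0.26, 0.39 and 0.12), for Runx+ versus kdrl+ in DMSO (0.42, 0.33 and 0.36) and for Lycorine versus DMSO in negative cells (0.28, 0.31 and 0.15), so the count with a replicate block is given beside those 3 results. They were not for Runx+ versus negative in DMSO (0.26, 0.37 and -0.09), nor for Lycorine versus DMSO in Runx+ cells (-0.01, -0.01 and -0.09) or in kdrl+ cells (0.07, -0.03 and -0.11). In simulated data of the size of these arrays, genes were drawn independently, each with 1 spread pooled over the groups. The test was tried there with 100 of 19247 genes changed at each of 2 sizes. At a log2 change of 2 it recovered between 83% and 93% of them in the 6 direct contrasts (93% for Runx+ versus negative, 93% for kdrl+ versus negative, 88% for Runx+ versus kdrl+, and 87%, 85% and 83% for Lycorine in Runx+, kdrl+ and negative cells). At a log2 change of 1 it recovered 36%, 33%, 28%, 32%, 31% and 30% in the same order. Each gene had the same spread in all simulated groups, so these 6 contrasts had equal power and their percentages differ only by the draw. In the real arrays spread was larger in DMSO than with Lycorine, so the percentages do not rank the real contrasts. For the 3 differences of effects, in the order Runx+ minus negative, kdrl+ minus negative and Runx+ minus kdrl+, it recovered 56%, 60% and 58% at a log2 change of 2, and 11%, 9% and 6% at 1. In 20 simulated runs with a list shifted by 0.5, camera called that list in 20 and another list in 1. Since the simulated genes were independent, these runs cannot show how camera at the preset behaves with correlated genes. In the real data the median estimated correlation of the lists was 0.34.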

Results

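The 18 arrays measured transcripts of 3 sorted cell fractions from 3 dpf zebrafish embryos treated with Lycorine or with DMSO. Runx+ cells carried the Runx1+23 enhancer reporter, kdrl+ cells the endothelial reporter, and negative cells neither, with 3 arrays for each sort and treatment. Values are log2 intensities, differences are given as log2 ± SE with n = 3 arrays per group, and adjusted p is from limma or, for lists, from camera. Array medians lay between 4.87 and 5.12. Replicates of DMSO groups correlated across genes at 0.921 to 0.962 (negative), 0.872 to 0.936 (Runx+) and 0.919 to 0.926 (kdrl+). Those of Lycorine groups correlated at 0.976 to 0.984, 0.961 to 0.980 and 0.975 to 0.982. Genes of liver, pancreas and gut scored highest in the 3 DMSO arrays numbered 2, with 2.56 (negative), 1.61 (Runx+) and 2.00 (kdrl+). DMSO Runx+ replicate 3 scored 1.1, and the remaining arrays at most 0.01.

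The comparison of kdrl+ with negative cells in DMSO asks which genes mark the endothelial reporter. Vessel genes were the most strongly raised. Of the 45 endothelial genes, 40 were higher in kdrl+ cells and 5 did not pass the test (43 were higher when adjusted over the list alone), with a median difference of 3.42. The reporter's own gene kdrl, a receptor for vascular endothelial growth factor, was higher by 3.73 ± 0.32 (adjusted p = 1.09e-06). The adhesion molecule pecam1a was higher by 4.61 ± 0.32, the Ets factor etsrp, which directs vascular fate, by 4.35 ± 0.32, and the receptor kinase tie1 by 4.34 ± 0.39. The endothelial list was called (camera adjusted p = 1.03e-64) and passed with an estimated correlation (adjusted p = 0.017). Others among the 10 largest rises were ptprbl (5.74 ± 0.36), myct1b (4.95 ± 0.33), mrc1a (4.48 ± 0.39), myct1a (4.39 ± 0.27), ptprb (4.32 ± 0.35), sele (4.2 ± 0.47) and RASIP1 (4.19 ± 0.30).

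HSPC, myeloid and lymphoid lists were also higher in kdrl+ than in negative cells in DMSO, while the erythroid list (median -0.35, 0 of 19 higher) and the thrombocyte list (0.23, 1 of 10 higher) were not called, both with adjusted p = 0.467. Of 21 HSPC markers, 11 were higher, 1 was lower and 9 did not pass (18 higher and 1 lower adjusted over the list alone), with a median of 1.3, and the list passed with an estimated correlation (adjusted p = 0.0319). The members that moved most clearly were coro1a (3.04 ± 0.40) and lcp1 (2.95 ± 0.47), actin regulators of leukocytes in general, ikzf1 (2.64 ± 0.38), a lymphoid transcription factor, and LYL1 (1.66 ± 0.24). The gene runx1 was higher by 0.82 ± 0.21 (adjusted p = 0.0203), while itga2b, an integrin of thrombocytes and early HSPC, differed by 0.93 ± 0.39 (adjusted p = 0.147). Of 23 myeloid genes 7 were higher and 16 did not pass (11 higher and 1 lower over the list alone), among them the neutrophil peroxidase mpx (2.87 ± 0.57) and srgn (2.62 ± 0.51). The myeloid list had adjusted p = 4.12e-05, and adjusted p = 0.423 with an estimated correlation. Of 14 lymphoid genes 3 were higher, led by the chemokine receptor ccr9a (3.43 ± 0.47), and tox was lower (-1.25 ± 0.37; 4 higher and 1 lower over the list alone), with adjusted p = 0.278 with an estimated correlation. Of 27 niche genes 9 were higher and 1 lower (10 higher and 3 lower over the list alone), among them jam2a (2.54 ± 0.24) and the chemokine receptors cxcr4b (3.21 ± 0.38) and cxcr4a (1.94 ± 0.27), with adjusted p = 0.466 with an estimated correlation.

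Genes of the nervous system and connective tissue were lower in kdrl+ than in negative cells in DMSO. Of 21 neural genes 13 were lower and 8 did not pass (18 lower over the list alone), with a median of -1.38. The neuronal RNA-binding protein genes elavl3 and elavl4 were lower by 3.05 and 2.43 log2 units (-3.05 ± 0.48 and -2.43 ± 0.32), and the synaptic gene syt1a was at -2.23 ± 0.32. Of 23 mesenchyme and cartilage genes 10 were lower (15 over the list alone), such as lum (-2.11 ± 0.37) and sparc (-1.07 ± 0.22), with a median of -1.15. The median of the epidermis list was -0.87, and 0 of its 19 members passed in limma, over all genes or over the list alone (tp63 -0.77 ± 0.30). These 3 lists had adjusted p = 0.209 (neural), adjusted p = 0.473 (mesenchyme and cartilage) and adjusted p = 0.771 (epidermis) with an estimated correlation. The 10 largest falls were en2b (-3.47 ± 0.36), a midbrain-hindbrain homeobox gene, slc6a11b (-3.15 ± 0.50), stmn1b (-3.07 ± 0.55), elavl3, islr2 (-3.04 ± 0.42), gpr3 (-3.02 ± 0.34), tmsb (-2.85 ± 0.49), tuba2 (-2.84 ± 0.43), lmo3 (-2.84 ± 0.61) and the glial glutamate transporter slc1a3b (-2.84 ± 0.63). Smaller list differences were called for ribosome biogenesis (median 0.28, 2 of 51 members higher both over all genes and over the list alone, ddx21 0.97 ± 0.24), cytosolic ribosomal proteins (0.09) and inflammation (0.29, 3 of 38 members higher, 1 over the list alone, mmp13a 2.65 ± 0.64). They had adjusted p = 0.771, adjusted p = 0.834 and adjusted p = 0.834 with an estimated correlation. The epidermis call was lost without DMSO kdrl+ replicate 1 (adjusted p = 0.0579) or 3 (0.0625) or DMSO negative replicate 2 (0.196). Inflammation was lost without DMSO kdrl+ replicate 3 (0.36) or DMSO negative replicate 1 (0.246). Ribosomal protein genes had adjusted p = 0.0817 without DMSO kdrl+ replicate 1, and ribosome biogenesis 0.0608 without DMSO kdrl+ replicate 3.

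In limma, 2023 of 19247 genes differed between kdrl+ and negative cells in DMSO, 865 higher and 1158 lower, and 1915 of them had arrays that did not overlap between the groups. Over all genes, 3960 (20.6%) did not overlap, against 10% by chance. Here and below the 10% holds for exchangeable arrays of equal spread. Spread was unequal between Lycorine and DMSO, so it is no exact reference for those contrasts. With the replicate block 2217 genes passed. The count was 1099 without DMSO kdrl+ replicate 3, 1091 without DMSO negative replicate 3 and 730 when only the 6 arrays compared were fitted, and after median centring 58.0% of calls were higher against 42.8%. Camera called 11 lists, 8 higher and 3 lower, of which 2 passed with an estimated correlation, and 20 without DMSO kdrl+ replicate 2 or 17 without DMSO negative replicate 3.

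**Figure D1:**
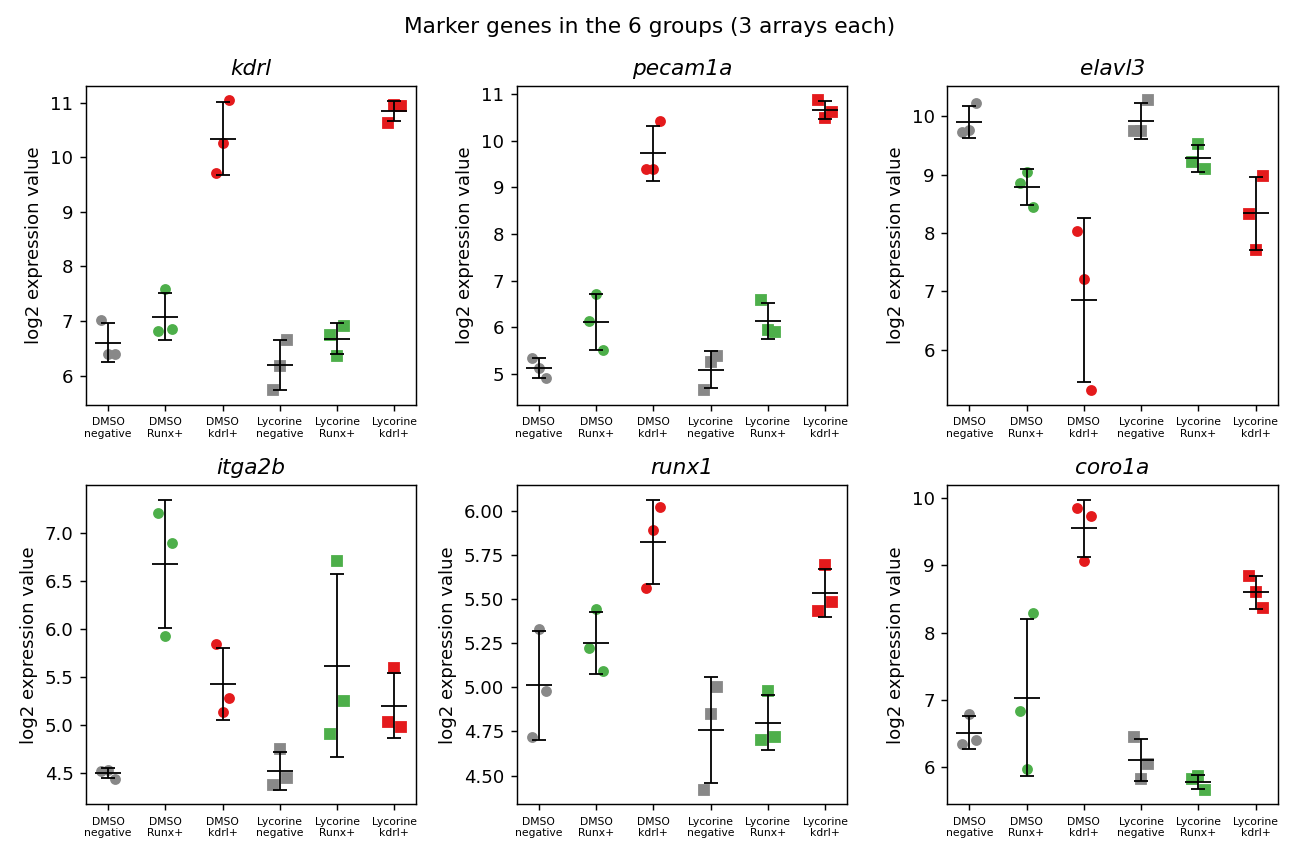
Log2 intensity of 6 marker genes (kdrl, pecam1a, elavl3, itga2b, runx1 and coro1a) on the 18 arrays, by sort and treatment, with circles for DMSO, squares for Lycorine, and the mean ± SD of the 3 arrays of a group. In DMSO, kdrl averaged 10.33 in kdrl+ cells against 7.08 in Runx+ and 6.61 in negative cells, and itga2b averaged 6.68 in Runx+ cells against 4.50 in negative cells.

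The comparison of Runx+ with negative cells in DMSO asks which genes mark the Runx1+23 reporter. A single gene passed, the class I major histocompatibility gene mhc1haa, which was higher in Runx+ cells by 1.72 ± 0.23 (adjusted p = 0.0113). The HSPC and thrombocyte integrin itga2b differed by 2.18 ± 0.39 with adjusted p = 0.0774, and it passed when adjusted over the HSPC list alone (adjusted p = 0.000551). The gene runx1 differed by 0.24 ± 0.21 (adjusted p = 0.697) and kdrl by 0.48 ± 0.32 (adjusted p = 0.586). The other genes with the smallest p did not pass and had adjusted p = 0.0774, namely cabp2b (1.42 ± 0.24), elfn2a (-1.17 ± 0.20), zbtb25 (-1.05 ± 0.18) and pcdh1g2 (-1.24 ± 0.22).

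Among blood lists, the HSPC markers stood higher in Runx+ than in negative cells in DMSO (median 0.19, camera adjusted p = 0.0154), with 0 of 21 members past limma's test over all genes and 2 adjusted over the list alone, itga2b and the repressor gfi1aa (0.71 ± 0.20). The HSPC scores were -0.24, -0.54 and 0.35 in Runx+ arrays against -0.32, -0.40 and -0.49 in negative arrays. Without DMSO Runx+ replicate 3 the mean difference of the list was 0.02 and the call was lost (adjusted p = 0.844), as it was without DMSO negative replicate 3 (adjusted p = 0.1). With the Lycorine arrays alone in the fit, a choice made after the data were seen, the median was 0.02 (adjusted p = 0.597). The erythroid list stood lower (median -0.80, camera adjusted p = 7.26e-05), with the embryonic globins hbbe2 (-1.69 ± 0.37) and hbae3 (-1.28 ± 0.32) lower over the list alone and 0 of 19 over all genes. Its score was 1.75 in DMSO negative replicate 1 against -0.03 and -0.05 in the other negative arrays (Runx+ -0.38, -0.61 and 0.45), and without that array the median was -0.13 and the call was lost (adjusted p = 0.299). Both lists had adjusted p = 0.876 with an estimated correlation. Lists of other tissues moved with the sort. Skeletal muscle (median 0.64, myhz1.1 1.82 ± 0.41 higher over the list alone), retina and lens (0.39, the rod transducin gene gnat1 1.19 ± 0.57) and epidermis (0.27, the claudin cldne 1.63 ± 0.67) stood higher in Runx+ cells. Neural genes (-0.55, elavl4 -1.21 ± 0.32 lower over the list alone) and mesenchyme and cartilage (-0.75, the growth factor receptor pdgfra -1.24 ± 0.50) stood lower. Muscle, neural and mesenchyme genes had adjusted p = 0.876 with an estimated correlation, and retina and epidermis had adjusted p = 0.927. The muscle scores of the 3 DMSO Runx+ arrays were 0.62, 1.01 and 1.44, against 0.22, 0.75 and 0.00 in negative arrays, and the retina and lens scores were 1.19, 1.41 and -1.15 against -0.01, 0.79 and -0.39. The retina call was lost without DMSO Runx+ replicate 1 (adjusted p = 0.448) or 2 (0.663) or DMSO negative replicate 1 (0.175) or 3 (0.409). Epidermis was lost without DMSO Runx+ replicate 2 (0.246) or 3 (0.433) or DMSO negative replicate 1 (0.242) or 3 (0.139).

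Among cell processes in the same comparison of Runx+ with negative cells in DMSO, genes of DNA replication (median -0.26) and mitosis (-0.27, CENPF -1.57 ± 0.35 lower over the list alone) stood lower. Genes of xenobiotic and oxidative stress (0.32, nqo1 1.33 ± 0.36 and cyp3a65 1.35 ± 0.39 higher over the list alone), sterol synthesis (0.25), the circadian clock (0.19, npas2 0.84 ± 0.16, hlfa 0.89 ± 0.25 and bhlhe40 0.88 ± 0.25 higher over the list alone) and nuclear-encoded oxidative phosphorylation (0.09) stood higher. The xenobiotic and sterol lists had adjusted p = 0.876 with an estimated correlation, and the other 4 had adjusted p = 0.927. The circadian call was lost without DMSO Runx+ replicate 3 (adjusted p = 0.14) or DMSO negative replicate 1 (0.297), and sterol synthesis without DMSO negative replicate 1 (0.0932). Oxidative phosphorylation was lost without DMSO Runx+ replicate 1 (0.753) or 2 (0.0697) or DMSO negative replicate 3 (0.65). Camera thus called 13 lists, 8 higher and 5 lower, and 0 with an estimated correlation.

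The gene count for Runx+ versus negative cells in DMSO depended on each of the 6 arrays compared. It was 568 without DMSO Runx+ replicate 1, 3 without DMSO Runx+ replicate 2, 25 without DMSO Runx+ replicate 3, 470 without DMSO negative replicate 2, and 0 without DMSO negative replicate 1 or 3. At an unadjusted p under 0.05 there were 2415 genes, and 2100 (10.9%) had arrays that did not overlap, against 10% by chance. Array weights gave 343 calls, and cyclic loess gave 11, of which 72.7% were higher.

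The comparison of Runx+ with kdrl+ cells in DMSO sets the Runx1+23 reporter against the endothelial reporter. Vessel genes were lower in Runx+ cells, with 42 of 45 endothelial genes past the test (44 over the list alone) and a median of -2.92, and the list passed with an estimated correlation (adjusted p = 0.015). The 10 largest falls were lyve1a (-4.54 ± 0.45), mrc1a (-4.50 ± 0.39), ptprbl (-4.28 ± 0.36), gpr182 (-4.23 ± 0.33), myct1b (-4.12 ± 0.33), calcrlb (-4.12 ± 0.37), etsrp (-4.10 ± 0.32), the scavenger receptor stab2 (-4.09 ± 0.27), tie1 (-4.01 ± 0.39) and the endothelial growth factor receptor kdr (-3.93 ± 0.31). The gene kdrl was lower by 3.25 log2 units (-3.25 ± 0.32), runx1 differed by -0.58 ± 0.21 (adjusted p = 0.109) and itga2b by 1.25 ± 0.39 (adjusted p = 0.0529). Epithelial genes were among the 10 largest rises, with the tight junction gene oclnb (2.88 ± 0.51), the connexin gjb8 (2.79 ± 0.38), the epithelial transcription factor grhl1 (2.75 ± 0.57) and the membrane protease st14a (2.68 ± 0.38). The others were il17rc (3.34 ± 0.69), dhrs13a.2 (2.89 ± 0.71), gfus.2 (2.77 ± 0.42), osbpl7 (2.72 ± 0.44), baiap2l1a (2.72 ± 0.63) and elovl7a (2.69 ± 0.55).

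HSPC, myeloid, lymphoid and erythroid lists were lower in Runx+ than in kdrl+ cells in DMSO, and the thrombocyte list was not called (median 0.24, 0 of 10 past the test, adjusted p = 0.461). Of 21 HSPC markers 11 were lower and 1 was higher (14 and 2 over the list alone), with ikzf1 at -2.54 ± 0.38, coro1a at -2.52 ± 0.40, lcp1 at -2.85 ± 0.47 and the blood and vessel factor lmo2 at -2.55 ± 0.48, and the list had adjusted p = 0.157 with an estimated correlation. Of 23 myeloid genes 7 were lower (9 over the list alone), such as mpx (-2.47 ± 0.57), and of 14 lymphoid genes 2 were lower (5 lower and 1 higher over the list alone), such as ccr9a (-3.00 ± 0.47), both with adjusted p = 0.225 with an estimated correlation. Of 27 niche genes 11 were lower and 1 higher (13 and 1 over the list alone), such as the integrin itga4 (-1.93 ± 0.28), with adjusted p = 0.225 with an estimated correlation. The erythroid list stood lower (median -0.69) with 0 of 19 members past the test (hbbe2 -1.03 ± 0.37) and adjusted p = 0.709 with an estimated correlation. Of 23 Notch pathway genes 7 were lower and 1 higher (8 and 1 over the list alone), with the arterial genes dll4 (-2.17 ± 0.34) and hey2 (-1.59 ± 0.30) among them, and adjusted p = 0.53 with an estimated correlation. The erythroid call was lost without DMSO Runx+ replicate 1 (adjusted p = 0.104) or 2 (0.0951) or DMSO kdrl+ replicate 1 (0.179). The Notch call was lost without DMSO Runx+ replicate 1 (0.0631) or 3 (0.0531) or DMSO kdrl+ replicate 3 (0.0562).

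Lists of several other tissues stood higher in Runx+ than in kdrl+ cells in DMSO. The lists of neural crest and pigment and of liver, pancreas and gut were not called. Of 21 neural genes 9 were higher (16 over the list alone), such as syt1a (1.59 ± 0.32) and elavl3 (1.93 ± 0.48). Of 19 epidermis genes 4 were higher (16 higher and 2 lower over the list alone), such as the claudins cldnb (2.22 ± 0.43) and cldne (2.87 ± 0.67). Of 23 muscle genes 2 were higher (4 over the list alone), myhz1.1 (1.49 ± 0.41) and desma (1.33 ± 0.38), of 19 retina and lens genes 1 (0 over the list alone), rcvrn2 (1.53 ± 0.44), and of 23 mesenchyme genes 1 (1 over the list alone), fn1b (1.39 ± 0.33). With an estimated correlation these lists had adjusted p = 0.287 (neural), 0.351 (epidermis), 0.45 (muscle), 0.619 (retina) and 0.785 (mesenchyme). Cholesterol synthesis genes were higher, 5 of 23 over all genes (8 higher and 1 lower over the list alone), among them hsd17b7 (1.49 ± 0.22), msmo1 (1.15 ± 0.23) and cyp51 (1.25 ± 0.29), with adjusted p = 0.287 with an estimated correlation. Of 32 circadian genes 2 were higher over all genes and over the list alone, cry3a (1.23 ± 0.23) and npas2 (0.81 ± 0.16), with adjusted p = 0.353 with an estimated correlation. Lower lists were DNA replication (median -0.51, orc1 -0.70 ± 0.20), mitosis (-0.38, aurka -0.96 ± 0.23), ribosome biogenesis (-0.41), cytosolic ribosomal proteins (-0.15) and immediate early genes (-0.16, the flow-responsive factor klf2a -1.74 ± 0.35 and nr4a1 -1.28 ± 0.35), with adjusted p = 0.488, 0.488, 0.45, 0.488 and 0.864 with an estimated correlation. Adjusted over the list alone, 0 of the replication, 1 of the mitosis, 0 of both ribosome lists and 2 of the immediate early genes were lower. The mesenchyme call was lost without DMSO Runx+ replicate 3 (adjusted p = 0.52) or DMSO kdrl+ replicate 2 (0.0532) or 3 (0.316). The retina call was lost without DMSO kdrl+ replicate 3 (0.348), and the immediate early call without DMSO Runx+ replicate 1 (0.968) or DMSO kdrl+ replicate 3 (0.65).

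In limma, 1623 genes differed between Runx+ and kdrl+ cells in DMSO, 834 higher in Runx+ and 789 lower, and 1437 of them had arrays that did not overlap. Over all genes 3134 (16.3%) did not overlap, against 10% by chance. With the replicate block 1867 genes passed. The count was 933 without DMSO Runx+ replicate 2, 708 without DMSO kdrl+ replicate 3 and 172 when only the 6 arrays compared were fitted, and after median centring 41.1% of calls were higher against 51.4%. Camera called 19 lists, 7 higher and 12 lower, and 1 passed with an estimated correlation.

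**Figure D2:**
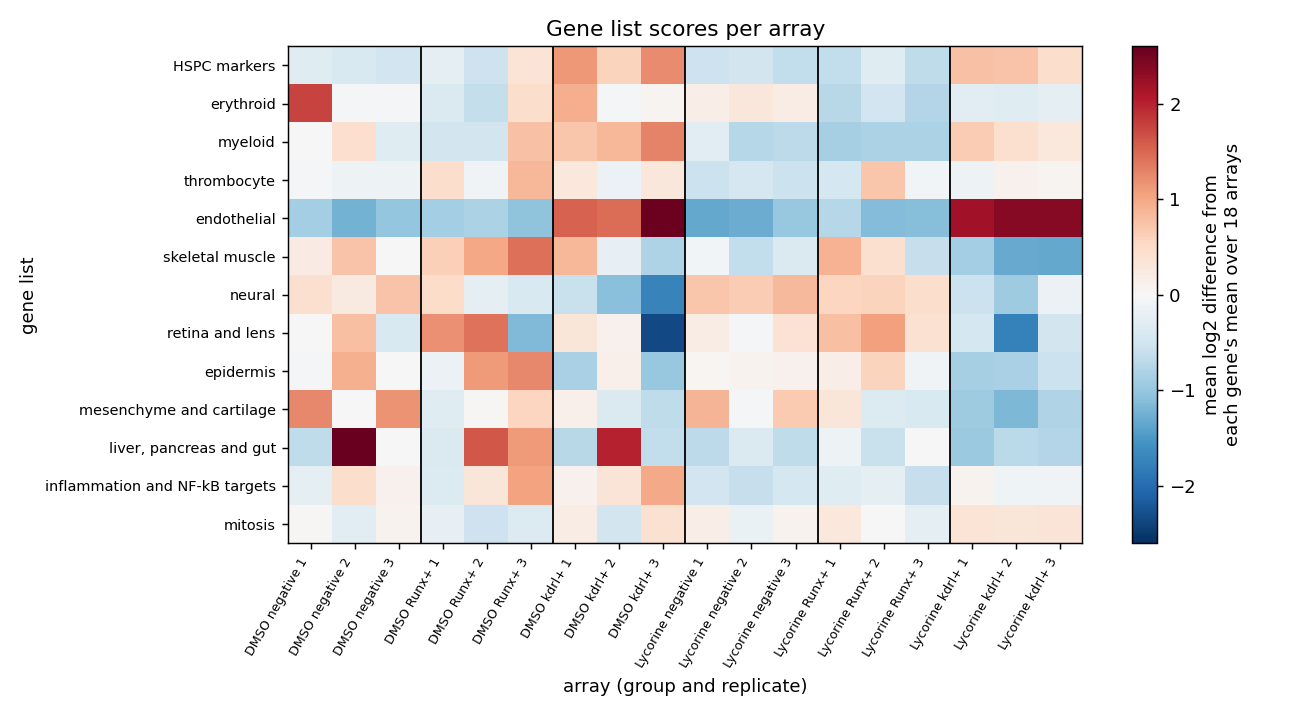
Mean log2 difference of 13 gene lists (rows) on each of the 18 arrays (columns), each gene taken relative to its mean over all arrays, with red above and blue below that mean. Endothelial scores of the 6 kdrl+ arrays ran from 1.45 to 2.54, and liver, pancreas and gut scores reached 2.56, 1.61 and 2.00 in the 3 DMSO arrays numbered 2.

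Lycorine was compared with DMSO in kdrl+ cells to find what it changed in the fraction with the endothelial reporter. In DMSO 7 of 23 myeloid genes were higher in this fraction than in negative cells. Its myeloid score changed by -0.51 (SE 0.21) with Lycorine. Whether the changes below lie in endothelial cells or in leukocytes of the fraction was not tested. Inflammatory signal genes were among those that fell, with the granulocyte growth factor csf3b at -2.34 ± 0.40 (adjusted p = 0.0421) and the chemokine ccl38.1 at -1.99 ± 0.26 (adjusted p = 0.0133). The coagulation factor X gene f10 fell by 1.43 log2 units (-1.43 ± 0.24, adjusted p = 0.0411), and pnpt1, a nuclease of mitochondria, was at -1.46 ± 0.24 (adjusted p = 0.0357). The clustered protocadherin gene pcdh1g29 (1.65 ± 0.27, adjusted p = 0.0357), the lectin gene hbl2 (1.40 ± 0.23, adjusted p = 0.0357) and ttf1.6 (1.41 ± 0.25, adjusted p = 0.043) rose. The neutrophil chemokine cxcl8a was at -1.71 ± 0.43 (adjusted p = 0.18) and passed adjusted over the niche list alone (adjusted p = 0.0228). The other niche genes did not pass, and the niche list was not called (median -0.27, adjusted p = 0.326).

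Lists moved in kdrl+ cells with Lycorine in camera, with 0 members past limma's test over all genes in each. Muscle genes were lower (median -1.29, 15 of 23 over the list alone, myl1 -1.85 ± 0.39 and pvalb2 -1.50 ± 0.32), and the muscle scores of the arrays were 0.86, -0.22 and -0.80 in DMSO and -0.88, -1.32 and -1.34 in Lycorine. Endothelial genes stood higher (median 0.47, 0 of 45 over the list alone, aqp8a.1 1.27 ± 0.34), as did neural genes (0.51, 4 of 21 over the list alone, elavl4 1.52 ± 0.32) and mitosis genes (0.30, 2 of 37 over the list alone, CENPF 1.66 ± 0.35 and top2a 0.96 ± 0.26). Notch pathway (0.16, dll4 1.01 ± 0.34) and proteasome genes (0.11) stood higher with 0 over the list alone. Lower lists over blood and inflammation were HSPC markers (-0.22, LYL1 -0.94 ± 0.24 and gata2b -1.14 ± 0.30 over the list alone), erythroid (-0.59), myeloid (-0.50, grna.1 -1.04 ± 0.23 and cxcr3.2 -0.72 ± 0.21 over the list alone), inflammation (-0.40, cxcl8a over the list alone) and interferon-stimulated genes (-0.22). Mesenchyme (-0.62, col1a1b -1.22 ± 0.35), liver, pancreas and gut (-0.88), hypoxia and glycolysis (-0.35) and oxidative phosphorylation (-0.27, cox5b2 -1.42 ± 0.34 over the list alone) stood lower too. With an estimated correlation the adjusted p of the called lists was 0.578 (muscle, endothelial, neural, myeloid, inflammation, interferon, hypoxia), 0.684 (HSPC, erythroid, mesenchyme, mitosis), 0.771 (Notch), 0.803 (liver) and 0.897 (proteasome, oxidative phosphorylation). The liver and pancreas genes stood at 2.00 in DMSO kdrl+ replicate 2 against -0.73 and -0.63 in the other DMSO kdrl+ arrays. Without DMSO kdrl+ replicate 3 the calls were lost for neural (adjusted p = 0.0718), HSPC (0.316), myeloid (0.0646), inflammation (0.0836), interferon (0.186), hypoxia (0.111) and proteasome genes (0.0718). Without DMSO kdrl+ replicate 2 they were lost for liver (0.695), mitosis (0.257), interferon (0.0753), proteasome (0.642) and Notch genes (0.237). Without DMSO kdrl+ replicate 1 they were lost for HSPC (0.065), erythroid (0.0598), oxidative phosphorylation (0.573) and Notch genes (0.143). Lycorine kdrl+ replicate 1 left out lost proteasome (0.0598), replicate 2 Notch (0.0725), and replicate 3 HSPC (0.287), interferon (0.0662) and Notch genes (0.259). Interferon, proteasome and Notch calls were also lost after cyclic loess, and without genes below the median.

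In limma 10 genes passed for Lycorine in kdrl+ cells, 3 higher and 7 lower, with 3 of the 10 known here only by clone identifiers. At an unadjusted p under 0.05 there were 2192, and 3052 genes (15.9%) had arrays that did not overlap, against 10% by chance. The count was 424 without DMSO kdrl+ replicate 3, 19 without DMSO kdrl+ replicate 2, 2 without DMSO kdrl+ replicate 1, 4 without Lycorine kdrl+ replicate 2 and 0 without Lycorine kdrl+ replicate 1 or 3. It was 1 when only the 6 arrays compared were fitted or when only the 14435 brightest genes were kept, and 6 without genes below the median. Camera called 15 lists, 5 higher and 10 lower.

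In Runx+ cells Lycorine was compared with DMSO to find what it changed in the fraction with the Runx1+23 reporter. Which cells this fraction holds is open. The gene runx1 did not pass against negative cells in DMSO (0.24 ± 0.21, adjusted p = 0.697). It lay at 5.09 to 5.44 against 4.72 to 5.33, near the array medians. HSPC markers stood lower than in kdrl+ cells (median -1.28). That list shares lmo2 and tal1 with the endothelial list and holds leukocyte genes such as coro1a, so this says little about HSPC content. The integrin itga2b did stand higher, at 5.93 to 7.21 in DMSO Runx+ against 4.44 to 4.54 in DMSO negative arrays, without passing over all genes. With Lycorine no gene passed in limma, with 0 at the threshold and 2600 at an unadjusted p under 0.05, and the smallest adjusted p was 0.0517 for mhc1haa (-1.50 ± 0.23). The next were insm2 (1.13 ± 0.19) and the annexin anxa11a (-1.33 ± 0.23) with adjusted p = 0.0744, and pcdh1g29 (1.49 ± 0.27) and elfn2a (1.08 ± 0.20) with adjusted p = 0.0876. Mitosis (median 0.40, top2a 0.81 ± 0.26), DNA replication (0.26, tk1 0.57 ± 0.21), neural (0.52, elavl4 1.65 ± 0.32 and slc17a6b 1.39 ± 0.33 over the list alone) and proteasome genes (0.15) stood higher with Lycorine in Runx+ cells. HSPC markers (-0.45, coro1a -1.25 ± 0.40 and itga2b -1.06 ± 0.39), erythroid (-0.41, hbbe2 -1.46 ± 0.37 over the list alone), myeloid (-0.67, mmp9 -1.96 ± 0.55) and inflammation genes (-0.69, noxo1a -1.43 ± 0.42) stood lower. So did muscle (-0.70), epidermis (-0.41), liver, pancreas and gut (-0.85), integrated stress response (-0.28, trib3 -0.82 ± 0.30) and xenobiotic stress genes (-0.45, nqo1 -1.29 ± 0.36). Adjusted over the list alone, 2 neural genes and 1 erythroid gene passed among these 13 lists. With an estimated correlation the lists had adjusted p = 0.773 (neural, myeloid, inflammation, xenobiotic), 0.782 (HSPC, muscle, epidermis, DNA replication, mitosis, integrated stress response), 0.863 (erythroid, liver) and 0.877 (proteasome). The 3 DMSO Runx+ arrays also enter Runx+ versus negative in DMSO, with the opposite sign, so what stood high in them tends to fall here. The genes mhc1haa, elfn2a, itga2b and nqo1 moved in opposite directions in these 2 contrasts. Of the lists called in both, only the erythroid list moved the same way. Whether the shared arrays alone give this was not tested. The liver, pancreas and gut scores of DMSO Runx+ replicates 2 and 3 were 1.61 and 1.1, against -0.38 in replicate 1. Without DMSO Runx+ replicate 3 the HSPC median was -0.19 and the calls were lost for HSPC (adjusted p = 0.421), erythroid (0.675), epidermis (0.378), liver (0.0733), integrated stress response (0.127), inflammation (0.0524) and proteasome genes (0.0609). Without DMSO Runx+ replicate 2 they were lost for epidermis (0.172), liver (0.273), integrated stress response (0.0798) and proteasome genes (0.172). Lycorine Runx+ replicate 1 left out lost erythroid (0.0656), DNA replication (0.0618) and proteasome genes (0.0656), replicate 2 liver (0.057), and replicate 3 epidermis (0.16) and integrated stress response genes (0.254). The integrated stress response call was also lost without genes below the median.

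The gene count for Lycorine in Runx+ cells was 1107 without DMSO Runx+ replicate 1 and 1 without DMSO Runx+ replicate 3. It was 952 with array weights, 20 with cyclic loess (35% higher), 3 after median centring, and 1 or 2 with the replicate block, the presumed pool as a random block, the filter at the median or the mean of a gene's rows. Arrays did not overlap for 2943 genes (15.3%), against 10% by chance.

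In negative cells, the background against which both reporters were set, 0 genes passed for Lycorine in limma, with 1302 at an unadjusted p under 0.05. That is not an absence of response, since with every probe row tested 39 rows without exactly 1 symbol were called higher (described below). The named genes with the smallest p were f10 (-1.36 ± 0.24, adjusted p = 0.307), the acetylcholine receptor subunit chrna6 (1.53 ± 0.29, adjusted p = 0.323), and uqcrfs1 (1.94 ± 0.39), zswim8 (1.12 ± 0.23) and cisd1 (-0.98 ± 0.20) with adjusted p = 0.407. Proteasome (median 0.19, psmc3 0.59 ± 0.22), neural (0.27, slc17a6b 1.43 ± 0.33 over the list alone), mitosis (0.08) and DNA replication genes (0.06, mcm10 0.77 ± 0.22) stood higher. Inflammation (-0.65, cxcl18b -1.04 ± 0.35 and cxcl8a -1.24 ± 0.43), myeloid (-0.58, irf8 -0.78 ± 0.25), niche (-0.27, cxcl12a -0.96 ± 0.35) and interferon-stimulated genes (-0.31, mxc -0.80 ± 0.28) stood lower. So did muscle (-0.69), liver, pancreas and gut (-0.91), integrated stress response (-0.23), immediate early (-0.20), hypoxia and glycolysis (-0.37, egln3 -0.90 ± 0.21 over the list alone) and circadian genes (-0.30, tefb -0.82 ± 0.21 and cry1b -0.71 ± 0.20 over the list alone). With an estimated correlation the lists had adjusted p = 0.712 (inflammation, myeloid, interferon, hypoxia), 0.716 (niche, muscle, neural, integrated stress response, circadian, proteasome), 0.782 (liver) and 0.842 (mitosis, DNA replication, immediate early). The liver, pancreas and gut score was 2.56 in DMSO negative replicate 2 against -0.67 and 0.01 in the other DMSO negative arrays. Without DMSO negative replicate 2 the calls were lost for myeloid (adjusted p = 0.0778), muscle (0.0517), liver (0.595), DNA replication (0.197), mitosis (0.172), integrated stress response (0.112), interferon (0.0778), immediate early (0.0517), hypoxia (0.0608) and circadian genes (0.0517). Without DMSO negative replicate 3 they were lost for niche (0.0528), DNA replication (0.0643) and immediate early genes (0.216). Lycorine negative replicate 1 left out lost DNA replication (0.559), mitosis (0.191), integrated stress response (0.0595) and immediate early genes (0.111). Replicate 2 left out lost niche (0.0628), integrated stress response (0.0966) and immediate early genes (0.344). DNA replication, mitosis and interferon calls were also lost after cyclic loess, and without genes below the median.

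Camera called 14 lists for Lycorine in negative cells, 4 higher and 10 lower, and 9 without DMSO negative replicate 2. The gene count was 0 with the replicate block, 9 with array weights and 1 without DMSO negative replicate 2, and 3247 genes (16.9%) had arrays that did not overlap, against 10% by chance.

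The Lycorine effects of the 3 sorts were set side by side. The growth factor gene csf3b differed by -1.46 ± 0.40 in Runx+, -2.34 ± 0.40 in kdrl+ and -1.16 ± 0.40 in negative cells, and f10 by -1.23 ± 0.24, -1.43 ± 0.24 and -1.36 ± 0.24. In the same order ccl38.1 differed by -0.35, -1.99 and -0.74, pnpt1 by -0.42, -1.46 and -0.65, pcdh1g29 by 1.49, 1.65 and 0.88, hbl2 by 0.36, 1.40 and 0.12, and ttf1.6 by 0.05, 1.41 and 0.36. Only the kdrl+ values passed. Thrombocyte, ER chaperone, heat shock and translation factor genes were called in none of the 9 contrasts, and with Lycorine in Runx+, kdrl+ and negative cells their medians were -0.32, -0.21 and -0.45 (thrombocyte), -0.02, 0.04 and -0.19 (ER chaperones), -0.01, 0.22 and -0.15 (heat shock) and -0.09, -0.11 and -0.05 (translation factors). Across 19247 genes, which are not independent replicates, the effects correlated at Pearson 0.45 and Spearman 0.41 between Runx+ and kdrl+, 0.61 and 0.58 between Runx+ and negative, and 0.46 and 0.42 between kdrl+ and negative cells. The same sign was found in 64.9%, 70.7% and 66.2% of genes. The sorts share no control arrays, but same-numbered arrays can share embryos. Between Runx+ and negative cells it was 0.38 without DMSO negative replicate 2. Between Runx+ and kdrl+ cells it was 0.36 without DMSO Runx+ replicate 1, 0.38 without Lycorine Runx+ replicate 2, and 0.52 and 0.31 without DMSO kdrl+ replicates 1 and 3.

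**Figure D3:**
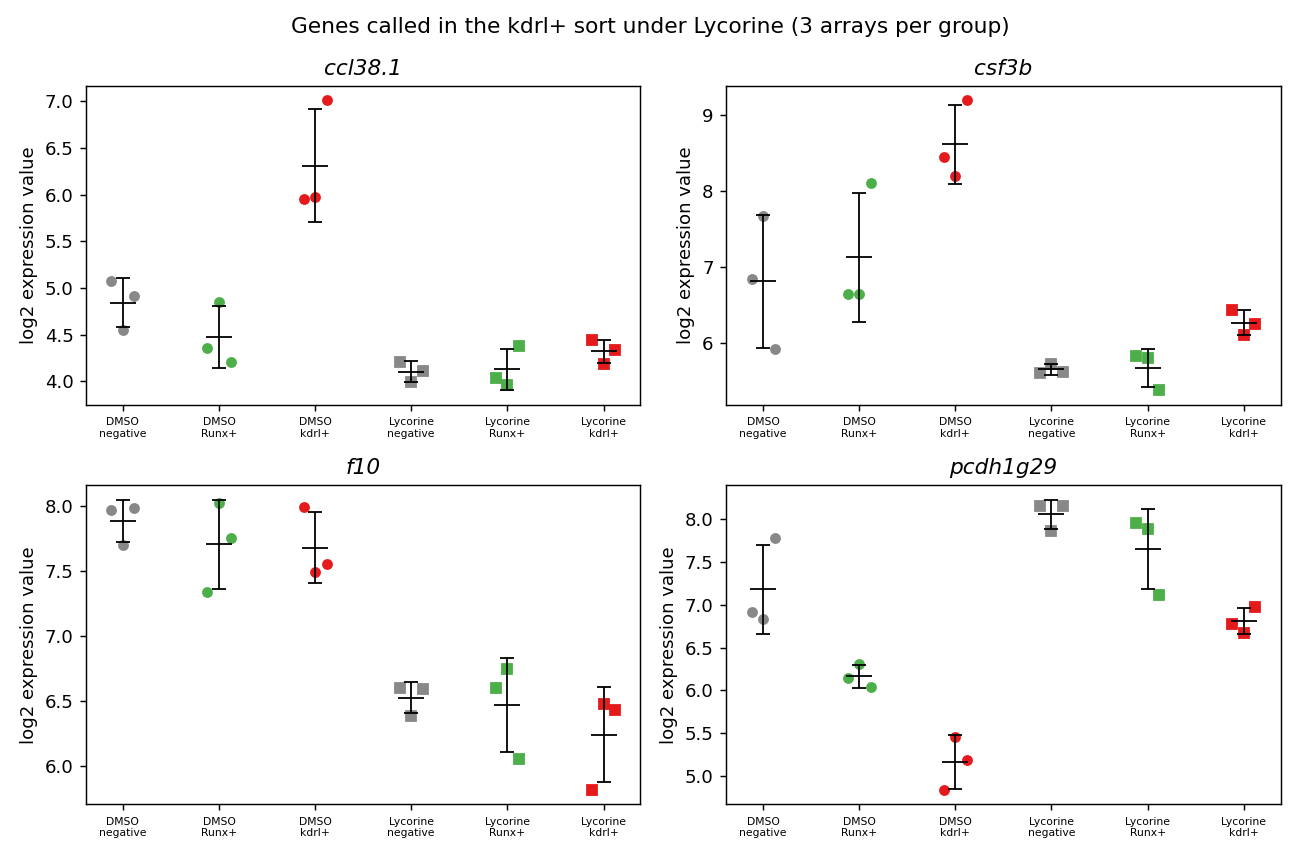
Log2 intensity of ccl38.1, csf3b, f10 and pcdh1g29 on the 18 arrays, by sort, with circles for DMSO, squares for Lycorine, and the mean ± SD of the 3 arrays of a group. In kdrl+ cells csf3b averaged 8.61 in DMSO and 6.27 with Lycorine, and pcdh1g29 averaged 5.16 and 6.81.

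The difference of Lycorine effects between sorts asks whether Lycorine acted differently in a reporter fraction. Endothelial genes differed by a median of 0.72 between the effects in kdrl+ and negative cells (camera adjusted p = 1.71e-11, erg 1.47 ± 0.44) and by -0.58 between those in Runx+ and kdrl+ cells (adjusted p = 7.97e-08, aqp8a.1 -1.46 ± 0.48). These had adjusted p = 0.88 and adjusted p = 0.894 with an estimated correlation. For kdrl+ minus negative cells camera also called muscle (-0.47, myl1 -1.47 ± 0.56), neural crest and pigment (-0.47), mesenchyme (-0.29), immediate early (0.32), circadian (0.40, nfil3-6 1.43 ± 0.48) and oxidative phosphorylation genes (-0.28), each with adjusted p = 0.88 with an estimated correlation. For Runx+ minus kdrl+ cells it called mesenchyme (0.47), p53 targets (-0.21, ccng1 -0.65 ± 0.28), xenobiotic stress (-0.38, nqo1 -1.13 ± 0.51) and circadian genes (-0.28), each with adjusted p = 0.894 with an estimated correlation. For Runx+ minus negative cells it called HSPC markers (-0.20, itga2b -1.08 ± 0.54), mitosis (0.20, MKI67 1.08 ± 0.55), xenobiotic stress (-0.22) and oxidative phosphorylation genes (-0.10), each with adjusted p = 0.985 with an estimated correlation. The endothelial differences, and those of immediate early and circadian genes for kdrl+ minus negative cells, were called with each single array left out. The immediate early call was lost with the 3 DMSO arrays numbered 2 left out together. For Runx+ minus negative cells the HSPC call was lost without DMSO Runx+ replicate 3 (adjusted p = 0.597), DMSO negative replicate 3 (0.203), Lycorine Runx+ replicate 1 (0.0778) or Lycorine negative replicate 2 (0.122). Mitosis was lost without Lycorine Runx+ replicate 1 (0.0977) or Lycorine negative replicate 2 (0.0697). Xenobiotic stress was lost without DMSO Runx+ replicate 2 (0.123) or 3 (0.364), DMSO negative replicate 1 (0.336) or 3 (0.262), Lycorine Runx+ replicate 1 (0.0565) or 3 (0.104) or Lycorine negative replicate 2 (0.137). Oxidative phosphorylation was lost without DMSO Runx+ replicate 1 (0.7), DMSO negative replicate 3 (0.578), Lycorine Runx+ replicate 2 (0.136) or 3 (0.186) or Lycorine negative replicate 1 (0.286). For kdrl+ minus negative cells DMSO kdrl+ replicate 1 left out lost muscle (0.492), neural crest (0.122), mesenchyme (0.27) and oxidative phosphorylation (0.543), and DMSO negative replicate 3 muscle (0.15) and neural crest (0.193). Neural crest was also lost without DMSO kdrl+ replicate 2 (0.0851) or Lycorine negative replicate 1 (0.0688). Mesenchyme was also lost without DMSO negative replicate 2 (0.57), Lycorine kdrl+ replicate 2 (0.0609) or Lycorine negative replicate 1 (0.236) or 3 (0.0702). For Runx+ minus kdrl+ cells DMSO kdrl+ replicate 1 left out lost mesenchyme (0.182), p53 (0.182), xenobiotic (0.138) and circadian genes (0.182), and DMSO Runx+ replicate 3 p53 (0.346), xenobiotic (0.106) and circadian genes (0.106). Mesenchyme was also lost without DMSO Runx+ replicate 1 (0.53), Lycorine Runx+ replicate 1 (0.359) or Lycorine kdrl+ replicate 2 (0.0648). So were p53 targets without DMSO kdrl+ replicate 2 (0.179), Lycorine Runx+ replicate 3 (0.102) or Lycorine kdrl+ replicate 2 (0.0648), and circadian genes without Lycorine Runx+ replicate 3 (0.0843). In all 16 of these list differences 0 members passed in limma, over all genes or over the list alone.

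In limma 0 genes passed for each of the 3 differences of effects, with 321 (Runx+ minus negative), 512 (kdrl+ minus negative) and 852 (Runx+ minus kdrl+) at an unadjusted p under 0.05. The smallest p belonged to bmpr1bb (1.59 ± 0.38, adjusted p = 1), hbl2 (1.28 ± 0.33, adjusted p = 0.999) and sh3tc2 (-2.05 ± 0.40, adjusted p = 0.871), and the difference for ccl38.1 between Runx+ and kdrl+ cells was 1.64 ± 0.37 (adjusted p = 0.983). Without DMSO kdrl+ replicate 3, 1 gene passed for kdrl+ minus negative and 5 for Runx+ minus kdrl+. When single arrays were left out, the list count for Runx+ minus negative ran from 1 to 13 around 4, with 13 without DMSO negative replicate 2, 9 without DMSO negative replicate 1, 8 without DMSO Runx+ replicate 2, 7 without Lycorine negative replicate 3, and 1 without DMSO negative replicate 3 or Lycorine negative replicate 2. For kdrl+ minus negative it ran from 5 to 15 around 7, with 15 and 13 without DMSO kdrl+ replicates 3 and 2, and 11 and 12 without DMSO negative replicates 1 and 2. For Runx+ minus kdrl+ it ran from 1 to 12 around 5, with 1, 12 and 10 without DMSO kdrl+ replicates 1, 2 and 3, 9 without DMSO Runx+ replicate 1, 8 without Lycorine Runx+ replicate 3, and 9 and 3 without Lycorine kdrl+ replicates 1 and 2.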

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

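The tests of unnamed probe sets and of the pattern they form were chosen after the result was seen, as were the levels of its genes. The list differences come from planned contrasts of Lycorine effects, in which the difference itself was tested with camera at the preset correlation. Between Runx+ and negative cells the effects differed for HSPC markers (-0.20), mitosis (0.20), xenobiotic and oxidative stress (-0.22) and oxidative phosphorylation (-0.10). Between kdrl+ and negative cells they differed for endothelial genes (0.72), skeletal muscle (-0.47), neural crest and pigment (-0.47), mesenchyme and cartilage (-0.29), immediate early genes (0.32), the circadian clock (0.40) and oxidative phosphorylation (-0.28). Between Runx+ and kdrl+ cells they differed for endothelial genes (-0.58), mesenchyme and cartilage (0.47), p53 targets (-0.21), xenobiotic and oxidative stress (-0.38) and the circadian clock (-0.28). With an estimated correlation 0 of these 16 differences passed in camera, and only the endothelial differences and those of immediate early and circadian genes for kdrl+ minus negative cells were called with each single array left out.

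These list differences are not set apart from other splits of the arrays. With sort labels permuted within each treatment, 99 of 100 splits called as many lists for Runx+ minus negative (real 4, highest other 19), 96 of 100 for kdrl+ minus negative (real 7, highest other 23) and 96 of 100 for Runx+ minus kdrl+ (real 5, highest other 24). For genes the real count was 0, which all 100 of 100 splits must reach in each difference, so that comparison says nothing (highest others 523, 1657 and 4461). Such splits mix real sort differences into the effects, so their high counts point to a structure of the samples, namely the sorts themselves. Chance is not excluded for the list counts.

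The endothelial list stood higher with Lycorine in kdrl+ cells (array scores 0.46 higher, SE 0.35). The checks of this pattern were chosen after the data were seen. If fewer cells of other types in an unchanged mix were the whole cause, their markers would move down together. The change of the neural score minus that of the muscle score was 1.71 (SE 0.33), from 0.59 (SE 0.41) for neural and -1.13 (SE 0.51) for muscle genes. The other types scored fell as muscle did, with mesenchyme at -0.66 (SE 0.26) and liver, pancreas and gut at -1.03 (SE 0.9). Epidermis was at -0.19 (SE 0.37), erythroid at -0.61 (SE 0.31) and myeloid genes at -0.51 (SE 0.21). Among these scores only the neural one rose and muscle fell most, and the pair was picked after the data were seen. It argues at most against fewer cells of an unchanged mix, and the other falls go with fewer cells of other types. Neural genes stood higher and muscle genes lower with Lycorine in Runx+ and negative cells too, so fewer cells of a changed mix cannot be told apart. The highest DMSO kdrl+ array exceeded the lowest Lycorine kdrl+ array by 0.36 in the endothelial score, so the spread among DMSO kdrl+ arrays may account for the pattern. A biological effect of Lycorine on endothelial cells stays open and was not tested separately.

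Probe sets without exactly 1 gene symbol were not part of the comparisons, and make up 44722 of 65528 (68.2%). In limma with p adjusted over all 65528, 154 of them were higher with Lycorine in Runx+ cells (18 lower), 327 in kdrl+ cells (44 lower) and 39 in negative cells (3 lower), with 5776, 6754 and 5257 at an unadjusted p under 0.05. Of probe sets with 1 symbol, 11, 27 and 0 were higher and 14, 23 and 1 lower in the same tests. Of the unnamed ones, 64 were higher in both Runx+ and kdrl+ cells (1.13 would be expected of independent lists), and 11 in all 3 sorts. The set 12981306, unnamed here, rose by 3.29 ± 0.30, 2.57 ± 0.30 and 2.97 ± 0.30 in Runx+, kdrl+ and negative cells, and 13257346, unnamed here, by 2.16 ± 0.27, 2.57 ± 0.27 and 2.04 ± 0.27. The 64 averaged 6.66, 5.78 and 5.40 in DMSO negative, Runx+ and kdrl+ cells, and 7.89, 7.45 and 6.98 with Lycorine.

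For the unnamed probe sets higher in Runx+ cells, the change was also measured in sorts where they had not been picked, although same-numbered arrays of the sorts can share embryos. Their median change was 1.13 in negative cells (96.8% above 0) and 1.22 in kdrl+ cells (96.1% above 0). A higher share of neural cells could raise them and cannot be told apart. Their median change in negative cells exceeded that of the neural list by 0.86 (SE 0.14), but they were picked for large rises and the list was not, and the neural gene slc17a6b changed by 1.43. After cyclic loess their median change in negative cells was 1.12, and 86 rather than 154 passed as higher in Runx+ cells. Cyclic loess started from the authors' normalized values, so it cannot exclude their normalization as a cause. Of the 154, 87% lay above the median level of all probe sets. That level averages all 18 arrays, among them those in which they were picked as high, so it cannot exclude noise in dim ones. Release from nonsense-mediated decay cannot be told apart either, since the 8 decay factor genes measured had medians of 0.13, 0.04 and 0.17 with 0 called in limma, the lowest being 0.04.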

How the results depend on the processing

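The 3 same-numbered DMSO arrays left out together, the Lycorine arrays alone, the mean of both treatments and the test on means of sorts were chosen after the data were seen. Single arrays left out gave lowest to highest gene counts of 0 to 568 for Runx+ versus negative in DMSO (1 with all arrays), 1091 to 2213 for kdrl+ versus negative (2023), 708 to 1916 for Runx+ versus kdrl+ (1623), 0 to 1107, 0 to 424 and 0 to 1 for Lycorine in Runx+ (0), kdrl+ (10) and negative cells (0), and 0 to 1 and 0 to 5 for the differences of effects kdrl+ minus negative and Runx+ minus kdrl+ (0 each). For the mean of sorts (2) the count ran 0 to 564 with 1 mean of 3 arrays left out. With single arrays left out, list counts ran 11 to 20 for kdrl+ versus negative (11), 9 to 19 for Lycorine in negative cells (14), and 1 to 13, 5 to 15 and 1 to 12 for the differences Runx+ minus negative (4), kdrl+ minus negative (7) and Runx+ minus kdrl+ (5). The agreement of Lycorine effects ran 0.31 to 0.52 for Runx+ and kdrl+ (0.45) and 0.38 to 0.66 for Runx+ and negative (0.61). With numbers 1, 2 and 3 of the DMSO arrays left out together, Runx+ versus negative had 91, 65 and 6 genes, Lycorine in Runx+ cells 1361 (number 1) and 2 (number 3), in kdrl+ cells 4 (number 1) and 707 (number 3), and in negative cells 4 (number 1) and 1 (number 2). Without number 3, kdrl+ versus negative had 725, Runx+ versus kdrl+ 773, and the differences kdrl+ minus negative 1 and Runx+ minus kdrl+ 4 genes. Lists were 8 for Runx+ versus negative (number 1; 13 with all), 18 for kdrl+ versus negative (number 2), 8 for Lycorine in negative cells (number 2), 7, 10 and 8 for Runx+ minus negative (numbers 1, 2 and 3), 15 for kdrl+ minus negative (number 3), and 12 and 10 for Runx+ minus kdrl+ (numbers 2 and 3), and the agreement of Runx+ and negative was 0.38 (number 2). An estimated correlation left 0, 2 and 1 lists for Runx+ versus negative, kdrl+ versus negative and Runx+ versus kdrl+ (19 at the preset), 0 each for Lycorine in Runx+, kdrl+ and negative cells (13, 15 and 14), and 0 each for the 3 differences. For Runx+ versus negative the gene count was 46 with the embryo pool as a random block, 0 with the compared arrays alone, 343 with array weights, 11 with cyclic loess and 10 with every row tested. For kdrl+ versus negative it was 730 with the compared arrays alone, 1310 with array weights and 3250 with every row tested, and for Runx+ versus kdrl+ 172 and 1065 with the first pair. For Lycorine in Runx+ cells it was 1 with the replicate block, 2 with the embryo pool as a random block, 952 with array weights, 20 with cyclic loess, 3 with median centring, 2 without genes below the median, 2 with the mean of all rows and 197 with every row tested. For Lycorine in kdrl+ cells it was 1 with the compared arrays alone, 1 with only the 14435 brightest genes, 6 without genes below the median and 421 with every row tested, and in negative cells 9 with array weights and 43 with every row tested. Cyclic loess gave 10 lists for Runx+ minus kdrl+. The same contrast among the Lycorine arrays gave 2 genes for Runx+ versus negative and 2455 for Runx+ versus kdrl+, the Lycorine arrays alone in the fit 33, 4640 (kdrl+ versus negative) and 5341, and the mean of both treatments 29, 4338 and 4461. Agreement over only genes called in either sort was 0.86 for Runx+ and kdrl+ and 0.87 for kdrl+ and negative, both over the 10 genes called in kdrl+ cells, which were selected for large effects. The mean of sorts had 0 genes with the replicate block, 7 with trend and robust, 4 with cyclic loess and 5 without genes below the median. For the 190 gene values named here, each with a contrast, call and direction were both the same in 186 with the replicate block, 188 with trend and robust, 175 with cyclic loess, 187 with median centring, 147 with array weights and 147 with the compared arrays alone. The cause of these changes was not tested.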

Other observations

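The contrasts among Lycorine arrays alone, the mean of both treatments and the mean of the 3 sorts were chosen after the result was seen. So were the erythroid, itga2b, muscle and retina tests of the Runx+ sort below. With the 9 Lycorine arrays alone in the fit, red blood cell genes were lower in Runx+ than in negative cells, with the globins hbbe2 (-2.85 ± 0.22, adjusted p = 0.000272) and hbae3 (-2.14 ± 0.21) and the heme synthesis gene alas2 (-2.02 ± 0.21) among 7 erythroid genes lower (10 over the list alone). The erythroid list had a median of -0.79 and adjusted p = 0.00852 with an estimated correlation. The HSPC list was not called (median 0.02, adjusted p = 0.597). The muscle myosin myhz1.1 (1.93 ± 0.31) was higher. So were the photoreceptor genes pde6ha (1.82 ± 0.27), pde6c (1.70 ± 0.29) and gucy2d (1.58 ± 0.23), which are not in the retina and lens list. That list had 0 of 19 members past limma's test (7 over the list alone), a median of 0.45 and adjusted p = 0.652 with an estimated correlation. In limma 33 genes passed (26 higher, 7 lower), 0 of them shared with DMSO. Only 1 gene had passed in DMSO, so that overlap says little. Across genes the Runx+ minus negative differences of the 2 treatments correlated at 0.59. In the mean of the DMSO and Lycorine contrasts 29 passed, among them hbbe2 (-2.27 ± 0.26), itga2b (1.64 ± 0.27) and mhc1haa (1.18 ± 0.16). For kdrl+ versus negative cells 4640 genes passed among Lycorine arrays alone, of which 1671 were among the 2023 of DMSO, all in the same direction.

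Runx+ cells stood close to negative cells, with 1 gene called between them in DMSO. If the Runx+ sort were an unselected sample of negative cells, their erythroid scores would match. The Runx+ score was -0.88 from negative cells with Lycorine (SE 0.09) and -0.73 in DMSO (SE 0.68). The erythroid list was picked for this after its values in the same arrays were seen, so the score is no separate test. Among all lists it passed camera in the Lycorine arrays with an estimated correlation (adjusted p = 0.00852). That argues against an unselected sample for the Lycorine arrays only. An exchange of Runx+ and negative arrays would mix their itga2b levels, but in DMSO the lowest Runx+ array lay 1.39 above the highest negative array (pooled SD 0.47). That test was first run on the Lycorine arrays, where the gap was 0.15, and was moved to DMSO after the values were seen. Muscle and photoreceptor cells in the Runx+ sort may add to its profile. Of 6 Runx+ arrays 3 lay above every negative array of their treatment in both scores (4 in muscle, 5 in retina), so the scores do not decide it. In the Lycorine arrays alone myhz1.1, pde6ha, pde6c, gnb3b, grk7a and gucy2d were among the 10 largest rises, which goes with such cells. The others of the 10 were nfil3-6, slc1a2a, slc17a7b and slc24a2. These genes were picked for large rises, so they are no separate test and the cause stays open.

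Each count was also compared with other splits of the same arrays. Splits of 3 against 3 arrays number 10, too few for a share under 0.05. The real split is 1 of them and is counted below, so a count of 1 means that no other split reached it. For Runx+ versus negative in DMSO 3 of 10 splits called as many genes (real 1), and the split of DMSO negative replicates 1 and 3 with DMSO Runx+ replicate 1 from the rest called 1719, which points to a structure of the samples other than the sort. For kdrl+ versus negative 1 split did (real 2023, highest other 3), and for Runx+ versus kdrl+ 1 (real 1623, highest other 800). For Lycorine in kdrl+ cells 1 did (real 10, highest other 2). In Runx+ and negative cells the real count was 0, which all 10 splits must reach, so that comparison says nothing (highest other 0). For lists, 6 splits did for Runx+ versus negative (real 13, highest other 15), 9 for kdrl+ versus negative (real 11, highest other 19) and 3 for Runx+ versus kdrl+ (real 19, highest other 20). For lists with Lycorine, 6 did in Runx+ (real 13, highest other 23), 9 in kdrl+ (real 15, highest other 19) and 5 in negative cells (real 14, highest other 15). For the correlation of Lycorine effects across genes 1 split of 10 did for each pair, with real values of 0.45, 0.61 and 0.46 and highest others of 0.40, 0.42 and 0.43.

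The 3 same-numbered arrays of a treatment were averaged over sorts and the 3 Lycorine means set against the 3 DMSO means. In limma csf3b (-1.65 ± 0.15) and f10 (-1.34 ± 0.13) were lower, both only just past the threshold (adjusted p rounds to 0.05). The glutamate transporter slc17a6b (1.3 ± 0.13, adjusted p = 0.0502) and pcdh1g29 (1.34 ± 0.15, adjusted p = 0.0664) did not pass. Of 10 splits only the real one called as many genes (real 2, highest other 0), too few splits for a share under 0.05. At an unadjusted p under 0.05 there were 3171 genes. With the replicate block 0 genes passed in limma, with 3213 at an unadjusted p under 0.05. Without the DMSO mean numbered 1 the count was 564, and it was 0 without any other mean.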
